A study of Mus musculus with 29 samples.

How the data were processed

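Uterine RNA of CD-1 mice was measured on 29 single-channel (Cy3) Agilent 4x44K arrays. Pups had received corn oil (CON) or genistein at 50 mg/kg/day (GEN) on postnatal days 1 to 5, and as adults their uteri were collected on gestation day (GD) 1.5, 3.5, 4.5 or 5.5. The 8 groups held 3 CON and 4 GEN arrays at GD1.5, 3 and 3 at GD3.5, 4 and 4 at GD4.5, and 4 and 4 at GD5.5. Exposure, day and replicate number were taken from the sample titles. The labels do not say that each sample came from a separate animal, so the p-values measure the spread between samples.

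The deposited scanner files give, per the file headers, the processed green intensity of each spot as extracted by Feature Extraction 9.5 from arrays labelled with 500 ng of total RNA. The series table deposited by the authors holds the same intensity values (largest difference 0%), so it gave no separate alternative, and 0 of its per-sample columns were left unused. Each array held 45018 spots, of which 43379 were not controls. The arrays lay on 8 slides read in 3 scans. The GD1.5 and GD3.5 samples shared slides 1 to 3, save GD3.5 CON 3, which lay alone on slide 4 in a scan of its own, and the GD4.5 and GD5.5 samples shared slides 5 to 8, so a change from GD3.5 to GD4.5 would coincide with the change of slides and was not tested. On slides 1 to 4 (13 arrays), 71.3 to 78.1% of spots were well above background and the 75th percentile of intensity was 1490 to 1840; on slides 5 to 8 (16 arrays) these were 65.5 to 80.9% and 734 to 995. No array had over 2 saturated spots, 34 to 149 spots per array carried the scanner's non-uniformity or population marks, and the slope of the spike-in controls was 0.918 to 0.982. Arrays of one group correlated at r = 0.959 to 0.995.

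Intensities were put on the log2 scale and the 75th percentile of each array's non-control spots was subtracted. Spots marked by the scanner as non-uniform or as population outliers were set to missing, and repeated spots of a probe were averaged. Gene names came from the RefSeq table through the probe's accession (22944 probes), its symbol (6664) or a synonym (3108), and otherwise from the scanner file (8458), which gave 27670 names for 41174 probes. Of these, 8914 had more than 1 probe, and the brightest probe stood for the gene. Printed coordinates are those of the array design on mouse build NCBI35 (mm7).

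Group means of all 29 arrays were fitted together with limma 3.58.1 (R 4.3.3, with statmod 1.5.0 and the data.table package, version 1.17.8), with moderated t-tests and Benjamini-Hochberg adjustment over the genes well above background on at least 3 arrays of the groups compared. A gene was called at an adjusted p under 0.05. The tests were GEN against CON on each of 4 days, the difference of that effect between successive days, and the change from GD1.5 to GD3.5 and from GD4.5 to GD5.5 within each exposure. The median standard error of a GEN to CON difference was 0.22, 0.24, 0.22 and 0.21 at GD1.5, GD3.5, GD4.5 and GD5.5. Where a probe was not well above background on any array of the dimmer group, the fold is given as "at least": the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. Such a fold is a lower bound.

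The lists, the 14 key genes, the comparisons and the alternatives were chosen before the data were examined, apart from those named as later additions. There were 26 lists with 366 genes, 359 of them with a value, and 13 key genes had a value. Each list with at least 4 measured genes was tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a day. Camera with a correlation estimated from the data and limma's fry were alternatives, and the members of each list were also adjusted over the list alone. The genes to name were set by rule: on each day the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between exposures and whose probe was well above background in both groups, up to 2 rises and 2 falls by lower bound, all key genes, and up to 4 called members of each called list. For day changes and differences between days the 4 largest each way and the key genes were named. Genes known only by a clone or accession name were counted, and are not named. Members of lists that were not called are given as examples, chosen after their values were seen.

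Alternatives were normexp background correction with an offset of 50, quantile normalization, the median (percentile 50) in place of the 75th percentile, only probes above background on all 29 arrays, the mean over a gene's probes, slide as fixed or random block, the replicate number as a block, only the arrays of the days compared, array weights, variance trend with robust fit, an added 2-fold threshold, and leaving out each array. Values within slides that held both exposures of a day stand beside the group differences. Added after the data were seen were normexp without spots whose local background exceeded their signal by over 100, weights estimated gene by gene, covariates for adipocyte and for simple epithelium markers, and the effect of genistein averaged over days. Every fit was repeated on other splits of the arrays, up to 100 per comparison.

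Replicate numbers were checked for pairing by the correlation of same-numbered samples' deviations from their group means. At GD5.5 all 4 pairs were over 0.1 (0.214 to 0.513), with 3 of the 4 pairs on one slide; at GD1.5, GD3.5 and GD4.5, 0 of 3, 0 of 2 and 1 of 4 pairs were. The labels name nothing that a number stands for, so the pairing at GD5.5 rests on the data alone. The pipeline was tested on simulated data with noise drawn independently for each gene and array, so correlation between genes and shared structure of samples were not simulated. Of genes given a log2 change of 1, 2 or 3 at GD1.5, 58.2%, 80.6% and 97.0% were called, with 9 false calls among 166, and the other days gave 59.7 to 61.2%, 85.1% and 92.4 to 95.5%. A downward shift of the gland list by 1 log2 unit was recovered at GD1.5, GD3.5 and GD5.5, and was missed at GD4.5 (adjusted p = 0.371). At GD3.5, 1 list that had not been shifted was called as well. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Some genes that the rule names are not reported here.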

Results

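At GD1.5, Hc, which encodes complement C5, was higher in GEN than in CON uteri (log2 2.48, SE 0.40, adjusted p = 0.0132). It stood at 0.09 ± 1.24 in GEN (n = 4) and -2.39 ± 0.19 in CON (n = 3, mean ± SD relative to the array's 75th percentile), and within the slides that held both exposures the difference was 2.56 to 3.96. Tdrd12, of the piRNA pathway, rose by 2.09 (SE 0.38, adjusted p = 0.0265; 1.13 to 2.18 within slides). Among genes well above background in both groups, the largest falls were in Mug1, a murinoglobulin protease inhibitor (log2 -4.58, SE 0.87, adjusted p = 0.0357; within slides -6.49 to -0.77), and in the keratin genes Krt86 (-3.75, SE 0.74, adjusted p = 0.0466; -5.64 to -1.03) and Krt23 (-3.33, SE 0.59, adjusted p = 0.0214; -5.25 to -1.60). In CON the level of Mug1 varied widely (-1.25 ± 3.42, against -5.83 ± 0.22 in GEN), as did that of Krt86 (-0.73 ± 2.21, against -4.48 ± 0.61). Spdef, an ETS transcription factor of secretory epithelium, fell by 2.71 (SE 0.42, adjusted p = 0.00864; -4.33 to -2.01 within slides). Atp6v1c2, which encodes a proton pump subunit, fell by 3.09 (SE 0.58, adjusted p = 0.0304) and Vsig1, an epithelial junction protein gene, fell by 2.82 (SE 0.52, adjusted p = 0.0265). Rptoros was at least 7.94-fold lower (adjusted p = 4.57e-04) and Ttr, the transthyretin gene, at least 1.42-fold lower in GEN (adjusted p = 0.0214).

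In all, 20 of 20504 genes were called at GD1.5, 5 higher and 15 lower in GEN, and 1258 were below an unadjusted p of 0.05. Mug1 and Krt86 lost their calls without any array but CON 1 (adjusted p up to 0.340 and 0.388), Tdrd12 without any but GEN 2 (up to 0.169), and Hc and Spdef without CON 2 (0.0948 each). Without CON 2 only 1 gene was called, without GEN 2 or GEN 3 there were 5 and 9, and without GEN 4 there were 34.

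The endometrial gland list fell at GD1.5 (median log2 -1.84 over 7 measured genes, or -1.80 with Ttr at its lower bound, all 7 negative; adjusted p = 1.60e-08, and adjusted p = 0.00251 with an estimated correlation). Only 1 member, Ttr, passed over all genes and 3 fell when adjusted over the list alone; Foxa2, a transcription factor of gland epithelium, had -1.84 (SE 0.41), and Sox9 -1.80 (SE 0.48). The implantation serine proteinase genes Prss28 (-3.25) and Prss29 (-3.59, SE 1.64) did not pass over the list alone and were higher than GEN in CON 2 and CON 3 only. Prss28 stood at -8.83, 3.54 and 5.36 in CON 1, CON 2 and CON 3 and at -3.90 to -2.84 in GEN, and Prss29 at -5.04, 5.08 and 5.95 in CON and -2.20 to -1.12 in GEN. CON 1 was thus below every GEN array for both, the one on its own slide included. Within slides the gland median was lower in GEN in 2 of 2, and the 4 GEN arrays lay between -2.77 and -1.26 of the CON mean. Simple epithelium markers had a median of -0.15 on that day. B and plasma cell markers rose by 1.10 (9 of 9 positive, adjusted p = 4.86e-08, and adjusted p = 0.0312 with an estimated correlation). Over all genes 0 members passed, and over the list alone 3 rose. Ms4a1 had 2.61 (SE 0.83), Jchain 2.43 (SE 0.91) and Pou2af1 2.23 (SE 0.75), and within slides the median was 0.59 to 1.90. Neutrophil markers rose by 2.04 (10 of 10 positive, 0 past the threshold, 1 over the list alone, adjusted p = 1.55e-08, but adjusted p = 0.0696 with an estimated correlation). Camp had 3.68 (SE 1.08), S100a8 3.02 (SE 1.32) and S100a9 2.92 (SE 1.26), and within slides the median was 1.08 to 4.25. Without CON 1, whose neutrophil median lay at -1.53, that of the list at GD1.5 was 0.57 (adjusted p = 0.00362).

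Adipocyte markers rose in the same samples (median 2.41, 8 of 8 positive, 0 past the threshold over all genes or over the list alone; adjusted p = 6.17e-05, but adjusted p = 0.487 with an estimated correlation), with Adipoq at 2.91 (SE 1.86) and Car3, a carbonic anhydrase of fat, at 2.79 (SE 1.37). The 4 GEN arrays had adipocyte medians of 4.35, 1.70, -0.05 and 3.45 and CON 1 had 1.62, and within slides the difference was -0.22 to 0.89. MHC class II genes rose by 0.82 (8 of 8 positive, 0 past the threshold, adjusted p = 0.00104, but adjusted p = 0.487 with an estimated correlation; 0.46 to 1.93 within slides), H2-Eb1 at 1.84 (SE 1.51) and Ciita at 1.14 (SE 0.59) among them. Macrophage and dendritic cell markers rose by 0.37 (11 of 12 positive, 0 past the threshold, adjusted p = 0.00169, but adjusted p = 0.663 with an estimated correlation). Fcgr1 had 0.87 (SE 0.42) and Ccr2 0.74 (SE 0.39), and within slides the median was 0.29 to 1.25. For macrophage and dendritic cell markers at GD1.5 the median was 0.12 without CON 1 (adjusted p = 0.228). Cell cycle genes rose by 0.25 (24 of 26 positive, 0 past the threshold, adjusted p = 0.0201, but adjusted p = 0.895 with an estimated correlation). Mki67 had 0.52 (SE 0.38) and Bub1 0.44 (SE 0.43), and within slides the median was -0.02 to 0.82. For cell cycle at GD1.5 the median was -0.01 without CON 1 (adjusted p = 0.579), and the call also ended without GEN 2 (0.0577) or GEN 4 (0.101). Estrogen response genes fell by 0.36 (14 of 19 negative, 0 past the threshold, adjusted p = 0.0223, but adjusted p = 0.680 with an estimated correlation). The aquaporin gene Aqp5 had -1.91 (SE 0.67) and Muc1 -0.77 (SE 0.41), and within slides the median was -0.70 to -0.11. The call for estrogen response at GD1.5 ended without CON 3 (adjusted p = 0.333), GEN 3 (0.163) or GEN 4 (0.101). Posterior tract regulators had a median of 0.12 (4 of 7 positive, 1 past the threshold, adjusted p = 0.00588, but adjusted p = 0.0696 with an estimated correlation; 0.03 to 0.18 within slides).

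**Figure D1:**
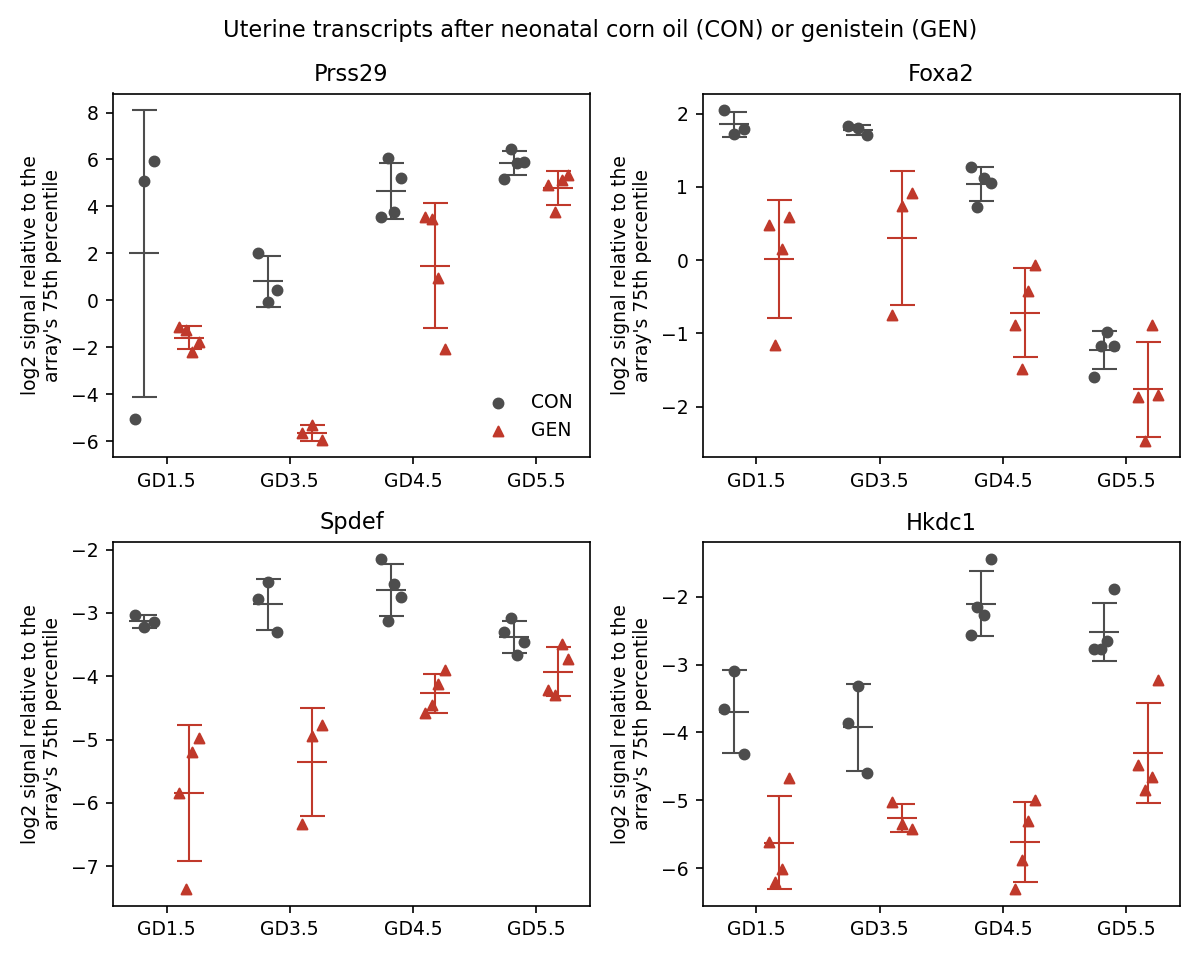
Log2 signal of Prss29, Foxa2, Spdef and Hkdc1 on each array relative to the array's 75th percentile, by gestation day and exposure. Bars show mean and SD.

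At GD3.5, Ltbp2, which encodes a binding protein of latent TGF-beta, was 4.16-fold higher in GEN (log2 2.06, SE 0.35, adjusted p = 0.0140; GEN -0.09 ± 0.29, CON -2.14 ± 0.34, n = 3 each; 1.56 to 2.28 within slides). The collagen gene Col12a1 rose by 1.04 (SE 0.18, adjusted p = 0.0202) and the myosin light chain gene Myl4 by 1.02 (SE 0.16, adjusted p = 0.00600). Mmp12, a macrophage metalloelastase gene, was at least 2.74-fold higher (adjusted p = 0.0315), without an exact size as CON was at background, but had -0.15 under normexp (adjusted p = 0.963). That normexp fit put the fifth percentile of signal at 401 on CON 3 and 154 on GEN 1, against 59.1 to 66.0 on unaffected arrays. Refitted without spots of high local background, the fifth percentile was 60.3 on CON 3 and 65.3 on GEN 1, and no sign change appeared for Mmp12. Of the mast cell tryptase genes, Tpsb2 fell by 3.34 (SE 0.62, adjusted p = 0.0315; -5.32 to -2.57 within slides) and Tpsab1 was at least 5.42-fold lower (adjusted p = 0.0319). Spdef fell by 2.48 (SE 0.45, adjusted p = 0.0237, -3.54 to -2.26 within slides), as did the tight junction gene Cldn8 (-1.94, SE 0.39, adjusted p = 0.0485) and Tuft1 (-1.47, SE 0.30, adjusted p = 0.0485). Sidt1 fell by 2.18 (SE 0.36, adjusted p = 0.0125) and Rptoros fell by 3.07 (SE 0.61, adjusted p = 0.0485). Hs3st3a1, a heparan sulfate sulfotransferase gene, was at least 5.00-fold lower (adjusted p = 0.0313) and Ttr at least 2.52-fold lower (adjusted p = 0.00600).

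Of 20401 genes 21 were called at GD3.5, 9 higher and 12 lower, and 1130 were below an unadjusted p of 0.05. Tpsb2 (adjusted p up to 0.222), Rptoros, Cldn8, Tpsab1 and Hs3st3a1 lost their calls without each of the 6 arrays in turn. Spdef lost its call without any array but GEN 4 (up to 0.177), and Ltbp2 without CON 3, GEN 1 or GEN 3 (up to 0.111). The count was 5 without CON 3, which lay alone on its slide and scan, 4 without GEN 3, 8 without GEN 1, 9 without GEN 4, 13 without CON 2, and 38 without GD4.5 GEN 4, which enters through the shared estimate of spread.

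The gland list fell at GD3.5 as well (median -2.39, or -2.33 with Ttr at its bound, 7 of 7 negative, Ttr called over all genes and 6 over the list alone; adjusted p = 3.29e-14, and adjusted p = 7.51e-05 with an estimated correlation; lower in GEN within 2 of 2 slides). Prss29 had -6.45 (SE 1.76), Prss28 -6.08 (SE 2.22), Wfdc3, of the whey acidic protein family, -2.39 (SE 0.59) and Sox9 -2.33 (SE 0.51). Simple epithelium markers had a median of 0.04. Eosinophil and mast cell markers fell by 0.73 (7 of 8 negative, Tpsb2 called; over the list alone 4 fell and 1 rose; adjusted p = 0.00259, but adjusted p = 0.159 with an estimated correlation; -1.03 to -0.79 within slides). The mast cell protease genes Cma1 and Cpa3 had -2.89 (SE 0.76) and -2.48 (SE 0.87), whereas Prg2, which encodes the eosinophil major basic protein, had 2.98 (SE 0.67). Smooth muscle markers rose by 0.30 (10 of 10 positive, 0 past the threshold, adjusted p = 0.00360, but adjusted p = 0.565 with an estimated correlation). Actg2 had 0.46 (SE 0.26) and Des 0.42 (SE 0.20), and within slides the median was 0.24 to 0.41. Neutrophil markers rose by 0.49 (9 of 9 positive, 0 past the threshold, 2 over the list alone, adjusted p = 0.00400, but adjusted p = 0.535 with an estimated correlation). Camp had 3.43 (SE 1.16) and Ngp 3.31 (SE 1.19), and within slides the median was -0.54 to 3.24. For neutrophil markers at GD3.5 the median was 0.15 without GEN 1 (adjusted p = 0.438).

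B and plasma cell markers rose by 0.30 at GD3.5 (8 of 9 positive, 0 past the threshold, adjusted p = 0.0383, but adjusted p = 0.535 with an estimated correlation). Jchain had 1.64 (SE 0.97) and Fcer2a 0.78 (SE 0.38), and within slides the median was -0.47 to 0.80. The call for B and plasma cell markers at GD3.5 ended without CON 1 (adjusted p = 0.144), CON 3 (0.195) or GEN 1 (0.170). Ovary markers fell by 0.36 (7 of 9 negative, 0 past the threshold, 1 over the list alone, adjusted p = 0.0375, but adjusted p = 0.217 with an estimated correlation). The zona pellucida gene Zp3 had -2.05 (SE 0.59) and Cyp11a1, the cholesterol side-chain cleavage enzyme gene, -2.49 (SE 1.04), and within slides the median was -0.42 to -0.19. The call for ovary markers at GD3.5 ended without CON 1 (adjusted p = 0.0857), CON 2 (0.133), CON 3 (0.426) or GEN 1 (0.123). For the posterior tract regulators the median (-0.08), the mean (0.71) and the upward test (adjusted p = 0.00403, but adjusted p = 0.0809 with an estimated correlation) differed in sign. Of its 7 genes 3 were positive, 1 was called, and 2 passed over the list alone; Pitx1, a hindlimb and pituitary homeobox gene, had 2.12 (SE 0.67) and Six4 0.82 (SE 0.34). Within slides the posterior median was -0.13 and 0.43.

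At GD4.5, falls were largest in Bpifb5, a secreted lipid-binding protein gene (18.5-fold lower, log2 -4.21, SE 0.78, adjusted p = 0.0272; GEN -3.64 ± 0.65, CON 0.57 ± 0.64, n = 4 each; -5.04 to -2.92 within slides), and Hkdc1, a hexokinase gene (11.5-fold lower, log2 -3.52, SE 0.39, adjusted p = 1.34e-04; GEN -5.62 ± 0.59, CON -2.10 ± 0.48; -3.87 to -3.09 within slides). The metabolic enzyme genes Cyp3a25 (-3.19, SE 0.60, adjusted p = 0.0291) and Akr1c19 (-2.70, SE 0.48, adjusted p = 0.0208) fell. Nlrp6, an inflammasome sensor of epithelium, fell by 3.07 (SE 0.52, adjusted p = 0.0155, -3.58 to -3.22 within slides), and Sp5, a transcription factor downstream of Wnt signalling, fell by 2.34 (SE 0.40, adjusted p = 0.0155, -3.06 to -2.07 within slides). Ttr was at least 2.52-fold lower (adjusted p = 0.0363). Banp, which encodes a nuclear matrix-binding protein, rose by 0.70 (SE 0.11, adjusted p = 0.0104; 0.62 to 0.73 within slides), Cyp2s1 by 0.89 (SE 0.16, adjusted p = 0.0272) and Hyou1, an endoplasmic reticulum chaperone gene, by 1.24 (SE 0.25, adjusted p = 0.0491), although another Hyou1 probe gave -0.78.

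Of 21620 genes 25 were called at GD4.5, 4 higher and 21 lower, and 2062 were below an unadjusted p of 0.05. Hkdc1 kept its call without any 1 array. Banp lost its call without CON 4 (adjusted p = 0.0569) and Nlrp6 without CON 1, CON 3, CON 4 or GEN 1, as did Bpifb5, Cyp3a25, Akr1c19, Sp5 and Hyou1, which also lost it without GEN 2. The count was 4 to 7 without CON 1, CON 3, CON 4 or GEN 1, 60 without CON 2, 87 without GEN 3, 65 without GEN 4 and 40 without GD5.5 GEN 4.

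The gland list was again lower at GD4.5 (median -2.11, which was that of Ttr, or -1.76 with Ttr at its bound, 7 of 7 negative, Ttr called and 4 over the list alone; adjusted p = 1.07e-07, and adjusted p = 0.00363 with an estimated correlation). Wfdc3 had -2.46 (SE 0.51, adjusted p = 0.0523) and Foxa2 -1.76 (SE 0.38, adjusted p = 0.0592), and the median was lower in GEN within 3 of 3 slides. The 4 GEN arrays lay at -2.06 to -1.72 and the CON arrays at -0.27 to 0.28. Simple epithelium markers fell as well, by 0.47 (10 of 11 negative, 0 past the threshold, adjusted p = 0.0173, but adjusted p = 0.640 with an estimated correlation). Cdh1, the E-cadherin gene, had -1.52 (SE 0.56) and Cldn4 -0.91 (SE 0.33), and within slides the median was -1.91 to -0.08. Eosinophil and mast cell markers fell by 0.66 (8 of 9 negative, 0 past the threshold, 4 over the list alone, adjusted p = 0.0173, but adjusted p = 0.528 with an estimated correlation). Cpa3 had -2.11 (SE 0.75) and Cma1 -1.88 (SE 0.66), and within slides the median was -1.34 to -0.39. Interferon response genes fell by 0.72 (13 of 14 negative, 0 past the threshold, adjusted p = 0.00160, but adjusted p = 0.640 with an estimated correlation). Mx1 had -1.56 (SE 0.60) and Irf7 -1.34 (SE 0.51), and within slides the median was -1.59 to 0.08. Red blood cell markers fell by 1.03 (4 of 4 negative, 0 past the threshold, adjusted p = 0.0255, but adjusted p = 0.610 with an estimated correlation). Slc4a1 had -1.13 (SE 0.58) and Alas2 -0.93 (SE 0.57), and within slides the median was -2.25 to 0.67.

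Smooth muscle markers fell by 0.26 at GD4.5 (10 of 10 negative, 0 past the threshold, adjusted p = 0.0408, but adjusted p = 0.640 with an estimated correlation). Smtn had -0.43 (SE 0.16) and Actg2 -0.41 (SE 0.23), and within slides the median was -0.61 to 0.08. Extracellular matrix genes rose by 0.11 (17 of 20 positive, 0 past the threshold, adjusted p = 0.00101, but adjusted p = 0.528 with an estimated correlation). Fn1, the fibronectin gene, had 0.65 (SE 0.20) and Fbn1 0.43 (SE 0.17), and within slides the median was -0.12 to 0.44. Decidualization and embryo attachment genes rose by 0.14 (17 of 24 positive, 0 past the threshold, adjusted p = 0.0173, but adjusted p = 0.640 with an estimated correlation). Angpt2 had 0.47 (SE 0.20) and Adm 0.46 (SE 0.19), and within slides the median was -0.21 to 0.70. Of 8 lists called on that day 2 rose and 6 fell. Apart from extracellular matrix, each shifted in the direction of its median in CON from GD4.5 to GD5.5. The same CON arrays enter both, which favours such likeness. Single arrays ended calls. Simple epithelium markers at GD4.5 had an adjusted p = 0.830 without GEN 2, smooth muscle markers at GD4.5 reached 0.437, decidualization and embryo attachment at GD4.5 reached 0.385, red blood cell markers at GD4.5 reached 0.165 without CON 1, and eosinophil and mast cell markers at GD4.5 reached 0.116 without GEN 1. The call for interferon response at GD4.5 ended without CON 1 (adjusted p = 0.0941) and that for extracellular matrix at GD4.5 without CON 4 (0.0795), and in all 3 to 5 lists were called without CON 1, CON 3, CON 4, GEN 1 or GEN 2.

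**Figure D2:**
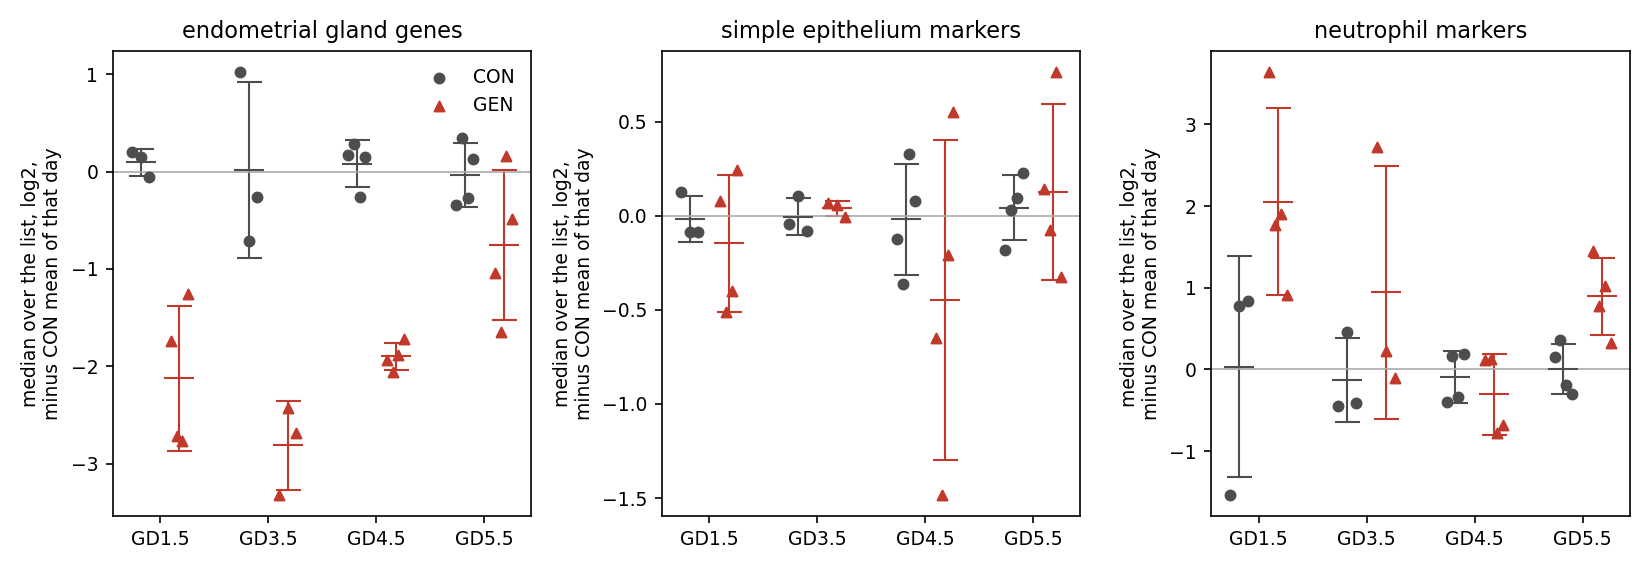
Median over the endometrial gland, simple epithelium and neutrophil lists on each array, relative to the CON mean of the day. Bars show mean and SD.

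At GD5.5, limma called 0 of 20828 genes (1125 below an unadjusted p of 0.05, smallest adjusted p = 0.0843). Foxa2 had -0.53 (SE 0.38; GEN -1.77 ± 0.65, CON -1.23 ± 0.26, n = 4 each; -1.29 to 0.21 within slides). The lactoferrin gene Ltf, an estrogen target of uterine epithelium, stood at 3.03 ± 2.00 in GEN and 0.52 ± 1.35 in CON. Without GEN 4 the count was 234. Without GD4.5 GEN 4, CON 2 or CON 4 the counts were 2, 4 and 1.

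Extracellular matrix genes rose at GD5.5 (median 0.15, 13 of 20 positive, 0 past the threshold, 5 over the list alone, adjusted p = 7.79e-05, but adjusted p = 0.360 with an estimated correlation). Col1a2 had 0.52 (SE 0.13), Col6a2 0.57 (SE 0.17) and Lum 0.60 (SE 0.18), and within slides the median was 0.02 to 0.37. MHC class II genes rose by 0.90 (7 of 8 positive, 0 past the threshold, adjusted p = 5.88e-04, but adjusted p = 0.539 with an estimated correlation). H2-Eb1 had 3.70 (SE 1.40) and H2-Ab1 1.40 (SE 0.61), and within slides the median was 0.27 to 2.10. Neutrophil markers rose by 0.74 (9 of 10 positive, 0 past the threshold, 1 over the list alone, adjusted p = 0.00146, but adjusted p = 0.539 with an estimated correlation). Retnlg had 2.30 (SE 0.54) and Mmp9 0.88 (SE 0.34), and within slides the median was 0.36 to 1.05. Macrophage and dendritic cell markers rose by 0.39 (12 of 12 positive, 0 past the threshold, adjusted p = 0.00216, but adjusted p = 0.741 with an estimated correlation). Csf1r had 0.50 (SE 0.31) and C1qa 0.48 (SE 0.36), and within slides the median was -0.0010 to 1.15. The gland list fell by 0.86, or 0.53 with Ttr at its bound (7 of 7 negative, 0 past the threshold over all genes or over the list alone, adjusted p = 0.0262, but adjusted p = 0.360 with an estimated correlation). Wfdc3 had -0.86 (SE 0.51), the GEN arrays lay at -1.64 to 0.16, and within slides the median was -2.07 to -0.43.

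Decidualization and embryo attachment genes fell by 0.26 at GD5.5 (19 of 25 negative, 0 past the threshold, 1 over the list alone, adjusted p = 0.0443, but adjusted p = 0.741 with an estimated correlation). Cryab had -0.94 (SE 0.25) and Alpl -1.46 (SE 0.49), and within slides the median was -0.54 to 0.29. Posterior tract regulators rose by 0.20 (3 of 5 positive, 0 past the threshold, 1 over the list alone, adjusted p = 0.0491, but adjusted p = 0.360 with an estimated correlation; -0.16 to 0.56 within slides). Apart from the gland list, each called list shifted against the direction of its median in CON from GD4.5 to GD5.5. The same CON arrays enter both, which favours such opposition. Of 7 lists called at GD5.5, 5 rose and 2 fell. With the replicate number as a block, the samples' numbers being correlated on that day, 0 genes and 4 lists were called (extracellular matrix, neutrophil, MHC class II and macrophage and dendritic cell lists). The block ended the calls for endometrial gland genes at GD5.5 (adjusted p = 0.0609), posterior tract regulators at GD5.5 (0.0782) and decidualization and embryo attachment at GD5.5 (0.0630). The call for endometrial gland genes at GD5.5 ended without CON 2 (adjusted p = 0.202), CON 4 (0.151), GEN 2 (0.134), GEN 4 (0.122) or CON 1 (0.0937). Macrophage and dendritic cell markers at GD5.5 had an adjusted p = 0.262 without GEN 3, 0.138 without CON 1 and 0.0586 without CON 4. Decidualization and embryo attachment at GD5.5 reached 0.425 and posterior tract regulators at GD5.5 reached 0.135, and 3, 4 and 4 lists were called without CON 1, CON 4 and GEN 3.

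Across the days, Foxa2, a transcription factor required for uterine gland formation, was called on none over all genes (-1.84, -1.48, -1.76 and -0.53; adjusted p = 0.0975 at GD1.5, 0.306 at GD3.5 and 0.0592 at GD4.5). Within slides Foxa2 was -3.20 to -1.61, -2.58 to -0.88 and -2.61 to -1.48 on the first 3 days. Adjusted over the 13 key genes alone, Foxa2 passed at GD1.5 (adjusted p = 0.00111), GD3.5 (0.0172) and GD4.5 (7.65e-04), and not at GD5.5 (0.454). Foxa2 at GD4.5 passed over all genes without GEN 3 (-1.85, adjusted p = 0.0495) or GEN 4 (-1.97, adjusted p = 0.0298). The effect on Foxa2 was not shown to differ between successive days (0.36 from GD1.5 to GD3.5, -0.28 from GD3.5 to GD4.5, and 1.22, SE 0.54, adjusted p = 0.642, from GD4.5 to GD5.5).

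The following key genes did not pass on any day. The progesterone and estrogen receptor genes had -0.31, 0.12, 0.17 and -0.09 (Pgr) and -0.20, 0.01, 0.23 and -0.17 (Esr1) at GD1.5, GD3.5, GD4.5 and GD5.5. The patterning genes had -0.01, -0.21, 0.16 and -0.18 (Hoxa10), -0.17, -0.26, 0.36 and -0.13 (Hoxa11) and -0.15, 0.27, -0.51 and 0.37 (Wnt7a), and Trp63, of squamous epithelium, 0.12, -0.82, 0.48 and 0.42. Cxcl15, a chemokine gene of glands, had -1.26, -1.50, -1.30 and -0.23. The mediators of progesterone action and decidualization had -0.25, 0.34, -0.78 and 0.51 (Ihh), -0.57, -0.57, 0.16 and -0.39 (Hand2) and -0.02, 0.27, 0.55 and -0.57 (Bmp2). Ltf had 0.06, 0.03, -2.93 and 2.52; without GD4.5 GEN 4, where it stood apart, it was -5.05 at GD4.5 (adjusted p = 0.0113).

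For the difference of the genistein effect between successive days, limma called 0 of 21063 genes (498 below an unadjusted p of 0.05) for GD1.5 and GD3.5 and 0 of 22557 for GD3.5 and GD4.5 (1069; smallest adjusted p = 0.0674). For GD4.5 and GD5.5 it called 1 of 22549 (1661 below an unadjusted p of 0.05), Banp, whose effect fell by 1.08 (SE 0.16, adjusted p = 0.0128), with GEN at 1.55 ± 0.10 and CON at 1.92 ± 0.06 at GD5.5 (n = 4 each). The Banp call ended with the replicate number as a block, with slide as a fixed block, with the median in place of the 75th percentile or with only the arrays of those days (0 genes called under each). It also ended without GD4.5 CON 4 (adjusted p = 0.0530), GD5.5 CON 1 (0.0519) or GD5.5 GEN 3 (0.0530), and without GD5.5 GEN 4 the count was 65. Among lists, 10, 6 and 10 of 26 differed between successive days at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.383). Rptoros, Sidt1, Spdef and Ttr were called lower at both GD1.5 and GD3.5 (0.00896 shared genes expected from independent lists), and Ttr also at GD4.5. The tests share each gene's estimate of spread and these days share slides, so the lists are not independent. Of the 20 genes called at GD1.5, 19 had the same sign at GD3.5, 18 at GD4.5 and 14 of 17 measured at GD5.5; of the 25 called at GD4.5, 20 of 22 had it at GD1.5, 20 of 23 at GD3.5 and 15 of 21 at GD5.5. Of the 21 called at GD3.5, 20 had it at GD1.5, 13 of 19 at GD4.5 and 9 of 16 at GD5.5.

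The 9 remaining lists were called on no day. Medians over the 4 days ranged from -0.11 to 0.04 for Mullerian duct patterning regulators, -0.22 to 0.15 for stratified squamous epithelium, -0.27 to 0.03 for progesterone response, -0.08 to 0.07 for the Wnt pathway and -0.45 to 0.25 for T and NK cell markers. They were -0.12 to 0.10 for endothelial markers, -0.30 to 0.12 for ciliated cell markers, -0.36 to -0.04 for conceptus and trophoblast markers, and -0.13 to 0.07 for immediate early and stress genes.

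**Figure D3:**
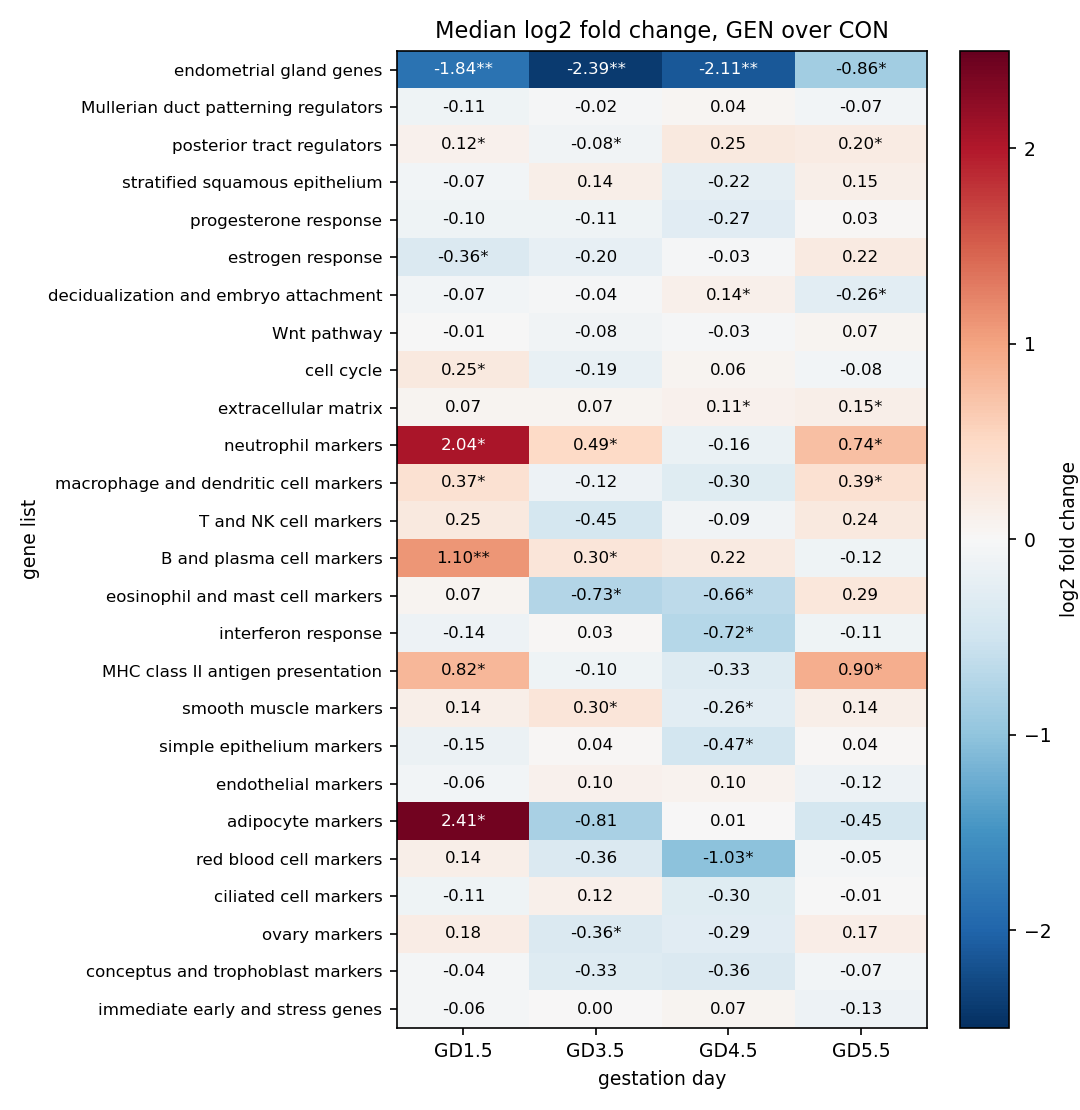
Median log2 difference between GEN and CON for each list and day. One asterisk marks an adjusted p under 0.05 at the preset correlation, and a double asterisk marks lists that kept it with an estimated correlation.

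From GD1.5 to GD3.5 in CON uteri, Areg, the progesterone-induced amphiregulin gene, rose by 6.03 (SE 1.35, adjusted p = 0.0157), Drd4, a dopamine receptor gene, by 5.37 (SE 0.80, adjusted p = 3.89e-04), Sox2ot by 5.04 (SE 1.00, adjusted p = 0.00649) and Olah by 4.79 (SE 0.97, adjusted p = 0.00762; n = 3 on each day). Kap, the kidney androgen-regulated gene, fell by 9.39 (SE 1.59, adjusted p = 0.00147). Clca1 (-6.97, SE 1.67, adjusted p = 0.0252), the matrilysin gene Mmp7 (-6.81, SE 0.97, adjusted p = 2.68e-04) and Upk3bl (-6.34, SE 0.64, adjusted p = 6.72e-06) fell next most. No key gene passed, Ltf at -4.21 (adjusted p = 0.178) included. In GEN uteri Areg rose by 5.44 (SE 1.26, adjusted p = 0.0121, n = 4 at GD1.5 and 3 at GD3.5), the glycine decarboxylase gene Gldc by 4.91 (SE 0.57, adjusted p = 1.84e-05), Olah by 4.89 (SE 0.91, adjusted p = 0.00201) and Acbd7 by 4.65 (SE 0.62, adjusted p = 7.80e-05). There Kap (-8.26, SE 1.49, adjusted p = 0.00157), Prap1 (-8.17, SE 0.56, adjusted p = 1.07e-08), Mmp7 (-7.65, SE 0.91, adjusted p = 2.16e-05) and Serpinb11 (-7.54, SE 0.81, adjusted p = 9.15e-06) fell most. Progesterone response genes rose by 0.65 in CON (2 of 19 rose, adjusted p = 0.239 with an estimated correlation) and 0.78 in GEN (5 of 19 rose, adjusted p = 0.125 with an estimated correlation). Estrogen response genes fell by 1.04 in CON (4 of 19 fell, adjusted p = 0.239 with an estimated correlation) and fell by 0.95 in GEN (5 of 19 fell, adjusted p = 0.421 with an estimated correlation). Cell cycle genes rose by 0.96 in CON (1 of 26 rose, adjusted p = 0.345 with an estimated correlation) and 0.61 in GEN (0 of 26, adjusted p = 0.525 with an estimated correlation).

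Other lists were called from GD1.5 to GD3.5 at the preset correlation. In CON, T and NK cell markers rose by 1.08 (2 of 15 rose, adjusted p = 0.336 with an estimated correlation) and endothelial markers by 0.39 (0 of 10, adjusted p = 0.336 with an estimated correlation). Neutrophil markers fell by 1.48 (0 of 8 past the threshold, adjusted p = 0.400 with an estimated correlation), interferon response genes fell by 0.74 (0 of 14, adjusted p = 0.529 with an estimated correlation) and stratified squamous epithelium genes fell by 0.42 (1 of 16 fell, adjusted p = 0.336 with an estimated correlation). In GEN, endothelial markers rose by 0.45 (4 of 10 rose, adjusted p = 0.125 with an estimated correlation) and immediate early and stress genes by 0.65 (0 of 9, adjusted p = 0.480 with an estimated correlation). Neutrophil markers fell by 1.68 (2 of 10 fell, adjusted p = 0.421 with an estimated correlation), macrophage and dendritic cell markers fell by 0.77 (1 of 12, adjusted p = 0.421 with an estimated correlation) and adipocyte markers fell by 3.00 (0 of 7, adjusted p = 0.421 with an estimated correlation). MHC class II genes fell by 0.87 (0 of 8, adjusted p = 0.480 with an estimated correlation) and interferon response genes fell by 0.73 (1 of 14, adjusted p = 0.480 with an estimated correlation).

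In CON 491 of 20615 genes changed between GD1.5 and GD3.5 (215 higher, 276 lower), and in GEN 1004 of 20395 (512 higher, 492 lower). Of 20236 genes tested in both, 140 rose in both (5.15 expected from independent lists) and 178 fell in both (6.56 expected), with a correlation of 0.720 across genes; the test of the difference between exposures, given above, called 0 genes. Both exposures share each gene's estimate of spread, so their lists are not independent. The CON count was 155 to 321 without any 1 of GD1.5 CON 1, CON 2, CON 3, GD3.5 CON 1 or CON 3, and 789 without GD4.5 GEN 4. The GEN count was 544 without GD1.5 GEN 1, 564 without GEN 2, 370 without GD3.5 GEN 3 and 345 without GEN 4. Areg in CON lost its call without GD1.5 CON 2, CON 3, GD3.5 CON 1 or CON 3 (adjusted p up to 0.105), and in GEN without GD1.5 GEN 2, GD3.5 GEN 3 or GEN 4 (up to 0.0874).

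From GD4.5 to GD5.5 in CON uteri, the decidual prolactin-family gene Prl8a2 rose 513-fold (SE of log2 1.04, adjusted p = 2.47e-06), Cyp11a1 by log2 7.89 (SE 0.90, adjusted p = 2.17e-06), Plekhg4 by 7.66 (SE 0.89, adjusted p = 2.58e-06) and Aoc1, the diamine oxidase gene, by 7.55 (SE 0.97, adjusted p = 8.04e-06; n = 4 on each day). The ion transport regulator gene Fxyd4 (-6.61, SE 1.15, adjusted p = 1.92e-04), the calbindin gene Calb1 (-5.48, SE 0.88, adjusted p = 8.52e-05), Alox15 (-4.73, SE 0.53, adjusted p = 1.69e-06) and Dleu7 (-4.54, SE 0.84, adjusted p = 3.37e-04) fell most. Among the key genes Bmp2, which drives decidualization, rose by 4.30 (SE 0.54, adjusted p = 5.57e-06) and Hand2 by 1.90 (SE 0.31, adjusted p = 9.85e-05), with Hoxa10 at 0.34 (adjusted p = 0.0329). Wnt7a (-2.83, SE 0.38, adjusted p = 1.33e-05), Cxcl15 (-2.66, SE 0.71, adjusted p = 0.00685), Foxa2 (-2.27, SE 0.38, adjusted p = 1.31e-04), Ihh (-1.80, adjusted p = 0.0126) and Trp63 (-1.36, adjusted p = 0.0199) fell. Decidualization and embryo attachment genes rose by 1.66 (17 of 25 rose and 2 fell, adjusted p = 0.449 with an estimated correlation) and cell cycle genes by 1.23 (25 of 26 rose, adjusted p = 0.498 with an estimated correlation). Simple epithelium markers fell by 1.24 (7 of 11 fell, adjusted p = 0.449 with an estimated correlation) and MHC class II genes fell by 2.15 (7 of 8, adjusted p = 0.498 with an estimated correlation). Macrophage and dendritic cell markers fell by 1.24 (10 of 12, adjusted p = 0.463 with an estimated correlation) and the gland list fell by 1.15 (3 of 7, adjusted p = 0.449 with an estimated correlation). Eosinophil and mast cell markers fell by 1.50 (6 of 9, adjusted p = 0.449 with an estimated correlation), interferon response genes fell by 1.18 (6 of 14, adjusted p = 0.498 with an estimated correlation) and smooth muscle markers fell by 0.77 (7 of 10 fell and 1 rose, adjusted p = 0.498 with an estimated correlation).

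In GEN uteri over the same interval, Prl8a2 rose 169-fold (SE of log2 1.04, adjusted p = 1.10e-04), Cyp11a1 by log2 7.08 (SE 0.90, adjusted p = 3.69e-05), Drd4 by 5.69 (SE 0.69, adjusted p = 2.71e-05) and Prl3d2, a placental lactogen gene, 48.4-fold (SE of log2 0.63, adjusted p = 1.71e-05; n = 4 on each day). The corneal keratin gene Krt12 (-4.21, SE 0.91, adjusted p = 0.00328), Calb1 (-3.61, SE 0.88, adjusted p = 0.00706), the immunoglobulin gene Iglv1 (-3.47, SE 1.18, adjusted p = 0.0382) and Ap3b2 (-3.29, SE 0.42, adjusted p = 3.69e-05) fell most. Bmp2 rose by 3.18 (SE 0.54, adjusted p = 4.96e-04) and Hand2 by 1.35 (adjusted p = 0.00476). Wnt7a (-1.95, adjusted p = 0.00151), Trp63 (-1.42, adjusted p = 0.0230) and Esr1 (-0.79, adjusted p = 0.00330) fell, and Foxa2 had -1.05 (adjusted p = 0.0501). Decidualization and embryo attachment genes rose by 0.97 (13 of 25 rose and 2 fell, adjusted p = 0.609 with an estimated correlation), cell cycle genes by 1.15 (15 of 26 rose, adjusted p = 0.609 with an estimated correlation), and simple epithelium markers fell by 0.82 (5 of 11, adjusted p = 0.609 with an estimated correlation). Extracellular matrix genes fell by 0.36 (7 of 20, adjusted p = 0.609 with an estimated correlation), macrophage and dendritic cell markers fell by 0.63 (1 of 12, adjusted p = 0.625 with an estimated correlation) and immediate early and stress genes fell by 0.50 (1 of 9, adjusted p = 0.609 with an estimated correlation).

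In CON 6642 of 21677 genes changed between GD4.5 and GD5.5 (3534 higher, 3108 lower), and in GEN 4540 of 20938 (2665 higher, 1875 lower). Of 20701 genes tested in both, 1937 rose in both (450 expected from independent lists) and 1390 fell in both (276 expected), with a correlation of 0.746. Here too the shared estimate of spread keeps the lists from being independent. In the test of the difference between exposures given above, Banp alone was called, and 0 genes with the replicate number as a block. The GEN count was 2361 without GD4.5 GEN 4, 2300 without GD5.5 GEN 1 and 2895 without GD5.5 GEN 4. Iglv1 lost its call without GD4.5 GEN 4 (adjusted p = 0.183) or GD5.5 GEN 1, GEN 2 or GEN 4, and Trp63 lost it in each exposure without any of 4 arrays.

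**Figure D4:**
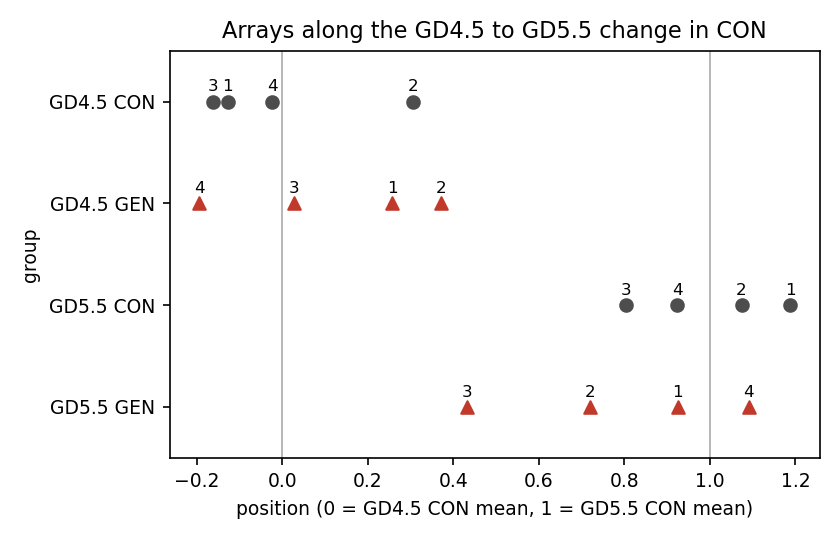
Position of each GD4.5 and GD5.5 array along the change between those days in CON, where 0 is the mean of GD4.5 CON and 1 that of GD5.5 CON. Numbers are replicate numbers.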

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

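The patterns weighed in this part, and the tests put to them, were chosen after the data were seen. They use fits that were planned (leaving out 1 array, values within slides) and covariates that were added (adipocyte and simple epithelium markers), and only for the 2 tests with the adipocyte covariate was the prediction written before the test's value was known.

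Endometrial gland genes were lower in GEN at GD1.5, GD3.5 and GD4.5. A lower share of epithelium in the GEN samples could lower them, but with simple epithelium markers as a covariate the gland median stayed at -1.75 at GD1.5, -2.40 at GD3.5 and -2.06 at GD4.5, which argues against it. The simple epithelium medians themselves were -0.15, 0.04 and -0.47, and within slides they were -0.67 to -0.25, -0.08 to 0.15 and -1.91 to -0.08. A difference between slides might also lower the gland genes, yet within the slides that held both exposures the gland list was lower in GEN in 7 of 7 slide and day pairs, nearest to 0 at -2.03, which argues against that as well. In 4 of the 7 the middle member was Ttr, which was at background in GEN, so only the direction is read from those. Fewer gland cells and less transcript per gland cell remain open as candidate explanations of an effect of neonatal genistein, and neither was tested.

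Samples of one group lay apart along the change from GD4.5 to GD5.5. This was taken over the 2415 genes called and at least 2-fold changed in CON under the given labels. That choice draws the CON arrays towards 0 and 1. GD4.5 CON lay at -0.16 to 0.31, GD4.5 GEN at -0.19 to 0.37, GD5.5 CON at 0.80 to 1.19 and GD5.5 GEN at 0.43 to 1.09. Slides may separate samples, but in GEN the arrays of one group on the same slide, a single pair in each, were 79.7% (GD4.5 GEN) and 74.8% (GD5.5 GEN) of their group's range apart. This argues against slides as the source in GEN. The CON arrays of a day all lay on different slides, so slides could not be tested there, and the slide 7 array was highest on both days (0.31 and 1.19). A swap of a GD4.5 and a GD5.5 sample could also give such a spread. In CON the days lay well apart (up to 0.31 against 0.80 and over), but the choice of genes favours that. No other split of these CON arrays called over 2442 genes, against 6642 with the labels given, which argues against a swap there. In GEN the highest GD4.5 position was 0.37 (GEN 2), nearer to GD4.5, but GD5.5 GEN 3 lay beside it at 0.43. The split with these samples exchanged called 4414 genes, against 4540 with the labels given, so a swap of them is not decided. A wrong label within one day stays open as well. The mean position was 0.12 (SD 0.25) in GEN against -0.0020 (SD 0.21) in CON at GD4.5. At GD5.5 it was 0.79 (SD 0.28) in GEN against 0.997 (SD 0.17) in CON. Choosing the genes on the CON arrays favours GEN means between the days. Hours since mating and the share of implantation sites in the tissue might differ between samples or exposures, and neither was tested.

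Neutrophil, B and plasma cell and adipocyte markers were called higher in GEN at GD1.5 at the preset correlation, and only B and plasma cell markers kept the call with an estimated one. Within slides the adipocyte difference was -0.22 to 0.89. Fat left on the GEN uteri could carry leukocytes, but with adipocyte markers as a covariate the neutrophil median was 2.08 and that of B and plasma cells 1.14, which argues against fat as the source of either. A single array may make the difference for neutrophils, since their lowest median was 0.57, without CON 1 (adjusted p = 0.00362). For B and plasma cells the lowest was 0.89, without GEN 2, which argues against a single array. No biological explanation was tested.

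Some samples stood far from the other samples of their group by Dixon's test, which sets the gap to the nearest sample against the group's range. It was made only in groups of 4 arrays, so GD1.5 CON, GD3.5 CON and GD3.5 GEN, with 3 arrays each, were not tested. Among genes these were Esr1 in GD1.5 GEN 4 (2.48, others 2.10 to 2.13), Trp63 in GD4.5 CON 2 (-5.47, others -3.92 to -3.60), Sp5 in GD4.5 GEN 4 (-2.40, others -4.50 to -4.18) and Ltf in GD4.5 GEN 4 (6.82, all others below 0). Among lists at GD1.5 they were estrogen response in GEN 1 (-0.085, others -0.51 to -0.46), B and plasma cell markers in GEN 2 (1.75, others 0.77 to 0.93) and conceptus and trophoblast markers in GEN 2 (-0.50, others -0.01 to 0.06). At GD4.5 they were progesterone response in CON 4 (-0.16, others near -0.02), estrogen response in GEN 4 (1.39, others -0.75 to -0.58), ovary markers in GEN 3 (0.063, others -0.49 to -0.44) and immediate early and stress genes in GEN 4 (1.15, others -0.04 to -0.01). At GD5.5 they were Mullerian duct patterning regulators in CON 1 (0.11, others 0.00 to 0.02) and adipocyte markers in CON 3 (3.06, others -0.87 to -0.76) and in GEN 1 (-1.57, others -0.36 to -0.21). Among array measures they were the spike-in slope of GD1.5 GEN 2 (0.937, others 0.975 to 0.976) and of GD4.5 GEN 3 (0.982, others 0.953 to 0.957), and the net negative control signal of GD4.5 CON 3 (25.3, others 31.3 to 32.3). For independent groups chosen without regard to spread, chance alone gives 4.75 such cases among the 95 gene groups tested, where there were 4. It gives 6.5 among 130 list groups, where there were 10, and 1.5 among 30 groups of array measures, where there were 3. Many of the genes were named because their arrays did not overlap between exposures, and GD4.5 GEN 4 recurs among the cases. The expected numbers are therefore only rough.

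The genistein effect on Banp differed between GD4.5 and GD5.5 by -1.08 in the test of the difference, and 0 genes were called there with the replicate number as a block.

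Each fit was repeated on other splits of the arrays, at most 100 drawn per comparison, and the number of splits, the real one included, with at least as many calls is given. At GD1.5 it was 2 of 35 for genes (real 20, highest other 32) and 13 of 35 for lists (real 9, highest other 13), so chance is not excluded. At GD3.5 it was 1 of 10 for genes (real 21, highest other 3) and 6 of 10 for lists (real 7, highest other 9), and for CON from GD1.5 to GD3.5 it was 1 of 10 (real 491, highest other 1), with too few splits to exclude chance. At GD4.5 it was 6 of 35 for genes (real 25) and 12 of 35 for lists (real 8, highest other 11), so chance is not excluded. There the split of CON 2, CON 4, GEN 1 and GEN 2 against the rest called 2289 genes, which points to a structure of the samples other than exposure. At GD5.5 it was 13 of 35 for lists (real 7, highest other 10), so chance is not excluded. For genes at GD5.5 it was 35 of 35, which a real count of 0 fixes in advance and which says nothing of chance. There the split of CON 3, GEN 1, GEN 2 and GEN 3 against the rest called 1123 genes. It differs from the exposure grouping only by the exchange of CON 3 and GEN 4, so it cannot tell exposure from another structure of the samples. Splits that part the 4 numbered pairs of GD5.5 called 0 to 70 genes and 3 to 7 lists. For the differences from GD1.5 to GD3.5 and from GD3.5 to GD4.5 it was 100 of 100 each, again fixed by a real count of 0 (highest other 8 and 418). For the difference from GD4.5 to GD5.5 it was 37 of 100 (real 1, highest other 1205), so chance is not excluded. No other split reached the real count for CON from GD4.5 to GD5.5 (1 of 35, real 6642, highest other 2442) or GEN from GD1.5 to GD3.5 (1 of 35, real 1004, highest other 602). The same held for the genistein effect averaged over days (1 of 100, real 243, highest other 9). Chance is unlikely for these, though so few splits cannot exclude it. For GEN from GD4.5 to GD5.5 it was also 1 of 35, but by a small margin (real 4540, highest other 4414, with GD4.5 GEN 2 beside GD5.5 GEN 1, GEN 2 and GEN 4).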

How the results depend on the processing

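Of the settings in this part, those added after the data were seen were normexp without spots of high local background, gene-by-gene weights and the adipocyte and simple epithelium covariates, and the other settings were planned. Of 2008 alternative values for 84 results of called genes, 374 fell short of the threshold and 2 changed sign. Of 887 for 31 results of called lists, 189 fell short and 19 changed sign. Of 3303 for 126 results of genes not called, 71 passed and 1 changed sign, and of 2095 for 73 results of lists not called, 91 passed. The gland list kept its call and direction in all 28, 27 and 30 alternatives at GD1.5, GD3.5 and GD4.5, and B and plasma cell markers at GD1.5 in all 28. Signal over background sets what can be called: with 65.5 to 80.9% of spots well above background on slides 5 to 8 and 71.3 to 78.1% on slides 1 to 4, a dim gene has only a lower bound or no test. Except where the setting itself has fewer genes, spots or samples, the cause was not tested.

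Counts of genes are given for GD1.5, GD3.5, GD4.5 and GD5.5 in that order. Normexp gave 5, 6, 14 and 9691, with 47 for the difference between GD4.5 and GD5.5, 232 for CON and 486 for GEN from GD1.5 to GD3.5, 11743 for GEN from GD4.5 to GD5.5, 135 for the average effect and 3 lists at GD5.5. Normexp shifted the median of all genes by -0.11 at GD3.5 and 0.28 at GD5.5, by 0.12 and 0.45 for differences between days, by 0.15 for CON from GD1.5 to GD3.5 and by 0.36 for GEN from GD4.5 to GD5.5. On 6 arrays it put the fifth percentile at 85.5 to 540, against 59.1 to 66.0 elsewhere, and those arrays held spots of high local background. Without such spots it gave 39, 64, 38 and 8, with 1 and 2 for the last 2 differences between days and 745 for CON from GD1.5 to GD3.5. Quantile normalization gave 5, 10, 47 and 1, with 4 for the difference between GD4.5 and GD5.5. Subtracting the median gave 36 at GD3.5 and 0 for that difference. Probes above background on all arrays gave 7 at GD1.5, 8 at GD3.5 and 1 at GD5.5, 1 and 3 for the last 2 differences, and 3 lists at GD3.5 and 4 at GD5.5. The mean over probes gave 3 at GD5.5 and 4 for the difference between GD3.5 and GD4.5. Slide as a fixed block gave 12 at GD1.5, 13 at GD3.5, 0 for the last difference, 118 for CON from GD1.5 to GD3.5, 1015 for GEN from GD4.5 to GD5.5 and 3 lists at GD3.5. As a random block it gave 49 at GD4.5.

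The replicate number as a block gave 9, 7 and 4 genes at GD1.5, GD3.5 and GD4.5, 0 for the difference between GD4.5 and GD5.5, and 4 lists at GD5.5. It changed no other count of calls by over 1.5 times. On each of the first 3 days only 1 same-numbered pair lay on one slide. Of their pairs only number 2 at GD4.5 was over 0.1 in the check of pairing (0.216). Only the arrays of the days compared gave 1, 12 and 7 on those days, 1, 4 and 0 for the differences, 938 for CON and 1683 for GEN from GD1.5 to GD3.5, 1504 for GEN from GD4.5 to GD5.5 and 3 lists at GD3.5. Array weights did not converge (0.234 for GD4.5 GEN 4 to 33.5 for GD1.5 CON 2) and gave 3422, 662, 114 and 166 genes, 386, 22 and 27 for the differences, 5268 for CON and 5522 for GEN from GD1.5 to GD3.5, 2212 for GEN from GD4.5 to GD5.5 and 1513 for the average effect. Weights fitted gene by gene gave 747, 638, 72 and 43, then 24, 17 and 3, 2762, 5452, 1659 and 837 for the same results. A variance trend with robust fit gave 48 at GD4.5, 1 at GD5.5, and 2 and 3 for the last 2 differences. Asking for a 2-fold change as well left 2415 for CON and 1357 for GEN from GD4.5 to GD5.5, 595 for GEN from GD1.5 to GD3.5 and 136 for the average. Camera with an estimated correlation called 2, 1, 1 and 0 lists and fry 3, 2, 1 and 0. The adipocyte covariate gave 8 at GD1.5. The simple epithelium covariate gave 35, 41 and 75 on the first 3 days, 5 and 3 for the last 2 differences, 851 for CON from GD1.5 to GD3.5 and 409 for the average.

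Leaving out 1 array gave 1 to 34, 4 to 38, 4 to 87 and 0 to 234 genes, and 8 to 13, 5 to 8, 3 to 11 and 3 to 8 lists on the 4 days. It gave 0 to 1, 0 to 4 and 0 to 65 for the differences between days, 155 to 789 for CON and 345 to 1226 for GEN from GD1.5 to GD3.5, 4957 to 7443 for CON and 2300 to 5747 for GEN from GD4.5 to GD5.5, and 166 to 351 for the average effect.

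Values that changed sign under normexp were Mmp12 at GD3.5 (-0.15), Cxcl15 at GD5.5 (1.24) and Trp63 in GEN from GD4.5 to GD5.5 (0.82). Each of these comparisons held some of the arrays with spots of high local background, and no sign change appeared for these genes without such spots. The posterior tract median at GD3.5 was 0.094 with slide as a fixed block, 0.71 without CON 2, 0.87 without CON 3, 0.44 without GEN 1, 0.32 without GEN 4 and 0.43 within slide 1, and ranged from -0.10 (without CON 1) to 0.87 without 1 array. Other list medians changed sign within a slide. At GD1.5 these were cell cycle (-0.020, slide 2) and adipocyte markers (-0.22, slide 1), and at GD3.5 neutrophil (-0.54) and B and plasma cell markers (-0.47), both on slide 3. At GD4.5 these were decidualization (-0.21, slide 8), extracellular matrix (-0.12, slide 5), interferon response (0.079, slide 6), smooth muscle (0.076, slide 8) and red blood cell markers (0.67, slide 6). At GD5.5 these were posterior tract regulators (-0.11, slide 6, and -0.16, slide 7), decidualization (0.29, slide 8) and macrophage and dendritic cell markers (-0.0010, slide 8).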

Other observations

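The genistein effect averaged over the 4 days was tested after the data were seen. Foxa2 was lower on average at -1.40 (SE 0.20, adjusted p = 4.84e-04). Also lower were Hkdc1 (-2.15), Spdef (-1.84), Sp5 (-1.73), Nlrp6 (-1.96), the glutathione peroxidase gene Gpx2 (-1.48), and the hair keratin genes Krt86 (-2.80) and Krt87 (-2.78), all called and of the same sign on 4 of 4 days. The gland list was lower at -1.52, with 5 of 7 members called (Ttr, which was at background on the GEN arrays and has no exact size, Wfdc3 at -1.52, Sox9 at -1.51, Foxa2 and Prss29 at -3.57; adjusted p = 2.59e-17, and adjusted p = 1.77e-05 with an estimated correlation). Rxfp2, a relaxin family receptor gene (1.56), C1qtnf3 (1.18), the serotonin transporter gene Slc6a4 (0.85) and the lymphatic growth factor gene Vegfc (0.37) were higher on all 4 days. In all, 243 of 23338 genes were called, 80 higher and 163 lower, and the highest count from the other splits drawn, 100 with the real one, was 9. Other lists were called higher on average at the preset correlation and lost the call with an estimated one. These were neutrophil markers (median 0.83, adjusted p = 3.91e-08, then 0.0953), extracellular matrix (0.12, 3.20e-07, then 0.0953), posterior tract regulators (0.058, 0.00241, then 0.0745) and MHC class II (0.35, 0.0113, then 0.808). The lists of stratified squamous epithelium (median -0.0064, adjusted p = 0.584) and simple epithelium (-0.12, adjusted p = 0.273) were not called.

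Singled out after their values were seen, and not as a tested group, the tryptase genes Tpsab1 (-2.34), Tpsb2 (-1.61) and Tpsg1 (-1.16), the protease genes Mcpt4 (-1.99) and Cma1 (-1.61), and the receptor genes Mrgprb2 (-1.56) and Kit (-0.60) were lower on average, and the eosinophil granule gene Prg2 was higher (1.61). The value of Tpsab1 is not an exact size, as it was at background on the GEN arrays of GD3.5. Of the genes singled out, Tpsb2, Cma1, Kit and Prg2 belong to the eosinophil and mast cell list, which was not called (median -0.10, 1 member higher and 3 lower, adjusted p = 0.202), and Tpsb2, Tpsg1, Cma1 and Mrgprb2 had the opposite sign at GD5.5 (0.29, 0.56, 0.22 and 0.46). Some antibody genes were higher: Jchain by 2.12, 21 genes of the immunoglobulin heavy chain region (chromosome 12, 110781031 to 113737877) at 1.54 to 2.13, and 6 of the kappa region (chromosome 6, 68233198 to 70744399) at 1.87 to 2.29. Such probes may share transcripts, so these are not independent genes, and the B and plasma cell list had 0.38 on average (adjusted p = 2.35e-04, but adjusted p = 0.0953 with an estimated correlation).

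Other groups of at least 3 neighbouring called genes, whose number expected by chance was not computed, were all lower in 6 places: 8 on chromosome 14 (38745869 to 40023342) at -2.45 to -3.63, 4 on chromosome 17 (23504096 to 23557404, Prss29 and the tryptase genes) at -1.16 to -3.57, 4 on chromosome 6 (121760668 to 122270248, Mug1 and Mug2 among them) at -1.47 to -2.55, 4 on chromosome 6 (129399454 to 130045499, Clec12b, Klri2, Klra5 and Klra6) at -0.90 to -2.76, 3 on chromosome 11 (112894739 to 113807347, Sox9, Cpsf4l and a clone) at -0.92 to -1.51, and 3 on chromosome 10 (61901912 to 62596136, Hkdc1, Pbld1 and Pbld2) at -0.86 to -2.15. The 8 on chromosome 14 are known only by clone, predicted or accession names. Their probes may share transcripts, so these may not be independent genes. A group of 3 on chromosome 2 (163955366 to 164472071, Wfdc15b, Slpi and Wfdc3) had 1 higher and 2 lower, and 3 on unplaced sequence had 2 higher and 1 lower.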
